A study of Homo sapiens with 6 samples.

How the data were processed

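RNA-seq libraries were made from PLC/PRF/5 cells infected with 1 of 2 adenoviruses, 3 libraries per virus. Per the labels' protocols, both viruses were of the AdEasy kind, 1 carrying SLC27A5 and the control carrying green fluorescent protein, total RNA was depleted of ribosomal RNA and fragmented, and libraries were read in paired ends on an Illumina sequencer. The deposited values are whole-number counts of reads per gene symbol, which the authors supplied as 1 table with a column per library and no normalization. The reads were placed on the GRCh38 genome, per the submitters' processing notes. The aligner, the counting program, the gene annotation and the handling of strand were not given in the sources used here. Columns were matched to samples by the group letter and replicate number in their names, which each occur in the title of 1 sample only, where the titles spell the gene as SCL27A5. All 6 sample columns were used. The labels' protocol speaks of libraries for pooled RNA samples and does not say that replicates came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

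The table held 51136 genes, of which 26382 had at least 1 count. Library totals ran from 21825542 to 27071250 counts, at which 3 counts correspond to between 0.111 and 0.137 CPM, counts scaled to the library total. Genes were kept with edgeR's filterByExpr at its default minimum count of 10, which left 15013. Counts were scaled by the trimmed mean of M-values (TMM), with factors from 0.990 to 1.010, and fitted with edgeR 4.0.16 in R 4.3.3 by a quasi-likelihood model with the virus as the only term. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg over all 15013 genes, and a gene was called changed at an adjusted p under 0.05. Standard errors (SE) are those of the log2 fold change in this model. Fold changes are AdSLC27A5 over AdGFP, and levels are TMM-scaled CPM, given as mean ± SD over 3 libraries.

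The 32 gene lists, the rule for the genes named, the test and most alternatives were fixed before the data were examined. Members that the table lists under another symbol were matched through a table of gene names, which placed 19 of them, and 12 of the 13 mitochondrially encoded mRNAs of that list were matched, while the remaining one, COX2, entered the share of counts only. Lists with at least 3 tested members were compared with all other genes by camera from limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over 31 lists. The test was repeated with an estimated correlation and with fry. The lists were NRF2 targets, bile acid synthesis and transport, fatty acid uptake and activation, fatty acid oxidation and PPARA targets, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, lipid peroxidation and ferroptosis, the unfolded protein response of the endoplasmic reticulum (ER), the ATF4 integrated stress response, p53 targets, G1/S and DNA replication, G2/M and mitosis, interferon response, NF-kB and inflammatory cytokines, epithelial junctions and keratins, mesenchymal genes, hepatocyte secreted proteins and identity, oncofetal and progenitor genes, glycolysis, hypoxia response, nuclear oxidative phosphorylation genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, immediate early genes, heat shock response, metallothioneins, and markers of immune, endothelial, fibroblast or stellate, and cholangiocyte cells, with the genes beside SLC27A5 on chromosome 19 as the last list.

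The named genes were SLC27A5, the 8 that rose and the 8 that fell most on the log2 scale among called genes with a mean log2 CPM of at least 1, no overlap between the groups' libraries and a symbol that is not a clone, LOC or LINC name, and 7 genes of the NRF2 pathway. Each list with at least 3 called members or called by camera gave up to 4 members with the smallest p, and each other list gave the 2 members with the highest counts. This named 104 genes, of which 3 are not reported here. Coordinates and overlapping genes were taken from GENCODE release 29 on GRCh38, 1-based.

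The tests were tried on simulated data first. In 5 sets of counts drawn for the comparison of AdSLC27A5 with AdGFP, with 14886 genes tested in the median set and 200 genes changed, edgeR called 49.2% of genes changed 1.2-fold, 90.0% of those changed 1.5-fold, 98.0% of those changed 2-fold and 99.6% of those changed 3-fold. Of all its calls 5.18% were false. camera called 5 of 5 lists shifted by 0.2 on the log2 scale and 0 of 149 lists not shifted. In all these sets genes were drawn independently of each other, with a biological coefficient of variation of 0.05 for every gene. The simulations therefore did not try the preset correlation of camera.

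Alternatives to the scaling were RLE size factors, upper-quartile scaling, total counts only, and scaling without SLC27A5. Other alternatives were no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, thinning to the smallest library, leaving out each library in turn, and for large changes edgeR's test against a fold of 1.5. Whether same-numbered libraries deviated together was checked by the correlation of their deviations from the group means.

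For a search of short sequences, the longest annotated 3' untranslated region (UTR) of 12301 genes, 99.3% of the protein-coding genes tested, was taken from GENCODE. Each of the 16351 words of 7 bases present in at least 30 genes was tested for an excess among called genes by a Poisson tail around a logistic model with UTR length, GC content and mean log2 CPM, with Bonferroni adjustment. This test replaced a normal approximation that called words in random lists of genes, and the words found with that approximation and with a plain count had by then been seen. A linear model with the same terms gave the shift in log2 fold change of genes holding a word, over 9536 genes with a mean log2 CPM of at least 3. On simulated shifts of -0.1 over those 9536 genes, 20 of 20 planted words were recovered first, and 2 of 20 shuffled data sets had a word past the limit. The excess test had a word past it in 0 of 20 random lists. Counts of genes are given with a 95% Wilson interval where a share is stated, which covers counting error only. Computations used Python 3.11.15 with scipy 1.17.1.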

Results

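The data are RNA-seq counts from PLC/PRF/5, an established human hepatoma cell line, infected with an adenovirus carrying SLC27A5 (AdSLC27A5) or with a control adenovirus carrying green fluorescent protein (AdGFP). Each group had 3 libraries, labelled replicates 1 to 3. SLC27A5 encodes a liver enzyme, also known as bile acyl-CoA synthetase or fatty acid transport protein 5, that activates bile acids and fatty acids by joining them to coenzyme A. The comparison asks which transcripts differ when hepatoma cells receive this gene. Total counts were 21991776, 27071250 and 21825542 in the AdGFP libraries and 23618248, 27007525 and 25552761 in the AdSLC27A5 libraries, and 15013 genes were tested. The first principal component of log2 CPM held 27.03% of the variance and put the AdGFP libraries between -14.6 and -9.08 and the AdSLC27A5 libraries between 10.98 and 13.2. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 2.82 and 5.92, so no pair was taken as 1 library deposited again. Pairs across the groups lay between 4.51 and 7.46, which overlaps that range. The 13 mitochondrially encoded mRNAs together took 8.01%, 7.95% and 7.85% of the counts in the AdGFP libraries and 8.46%, 7.78% and 8.56% in the AdSLC27A5 libraries.

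SLC27A5 was 8.25-fold higher in the AdSLC27A5 libraries, at 96.4 ± 10.6 CPM against 11.7 ± 0.941 CPM (SD, n = 3 each), a log2 fold change of 3.04 (SE 0.081; edgeR adjusted p = 1.3e-15). Its counts were 252, 298 and 281 with AdGFP and 2538, 2399 and 2308 with AdSLC27A5, so every library matched its label. The gene lies on the minus strand of chromosome 19 from 58479512 to 58512413 (GRCh38) and overlaps ZNF446 on the other strand. Counts per gene do not separate transcripts of the vector from those of the cell's own gene. None of the 13 tested genes beside it passed the edgeR test, and their median log2 fold change was -0.0055. Among these neighbours, TRIM28 had a log2 fold change of 0.020 (SE 0.043), and the list was not called (camera adjusted p = 0.47).

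**Figure D1:**
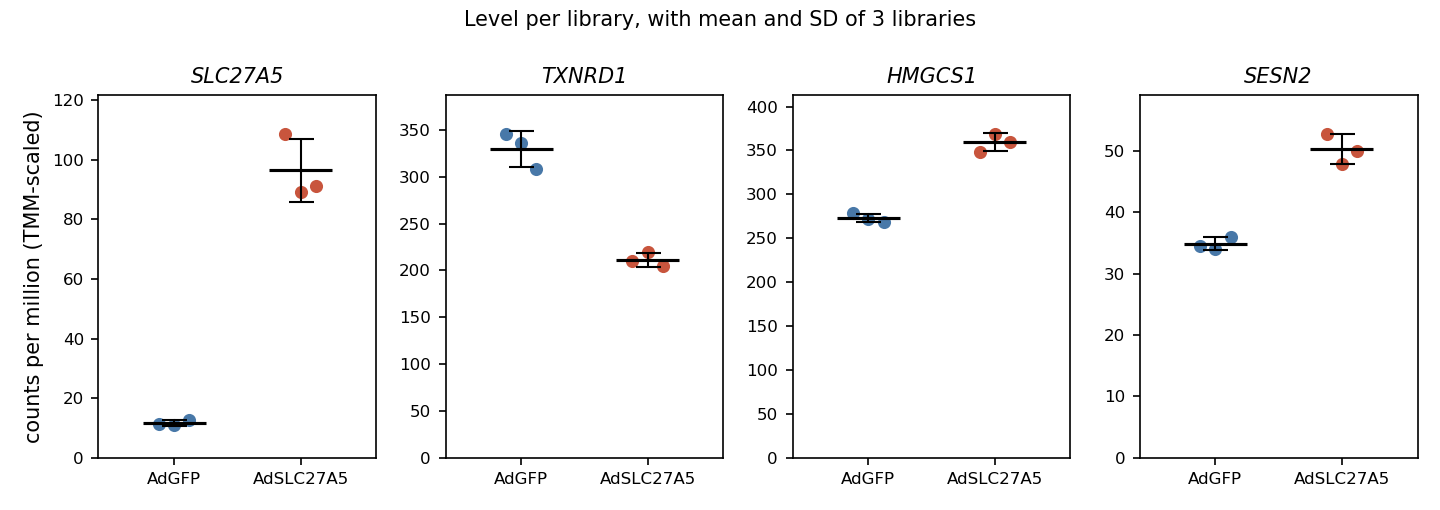
CPM after TMM scaling of SLC27A5, TXNRD1, HMGCS1 and SESN2 on separate axes that start at 0, with 1 point per library, the mean as a bar and the SD of 3 libraries as whiskers, for AdGFP and AdSLC27A5. SLC27A5 lay between 89.2 and 108.6 CPM with AdSLC27A5 and between 10.97 and 12.8 CPM with AdGFP, and no library overlapped the other group for any of the 4 genes.

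Besides SLC27A5, 110 genes rose and 186 fell, so that 297 genes changed (edgeR adjusted p under 0.05). Most changes were small: the median size was 0.27 on the log2 scale for genes that rose and 0.35 for genes that fell. TXNRD1, a cytosolic thioredoxin reductase, and IGFBP1, a secreted binder of insulin-like growth factors, had the lowest p-values among genes that fell. Genes of cholesterol synthesis and of the ATF4 stress response were among those that rose. At an unadjusted p under 0.05 there were 2031 genes, and the libraries of the groups did not overlap for 19.2% of tested genes, where chance gives 10%. With total counts only as the scaling, 68 genes rose and 234 fell, and without a filter on low counts 504 genes changed. The number changed was 172 without AdGFP replicate 3, 157 without AdSLC27A5 replicate 2 and 134 without AdSLC27A5 replicate 3, and 70 genes rose without AdGFP replicate 2, with more genes falling than rising in each case.

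**Figure D2:**
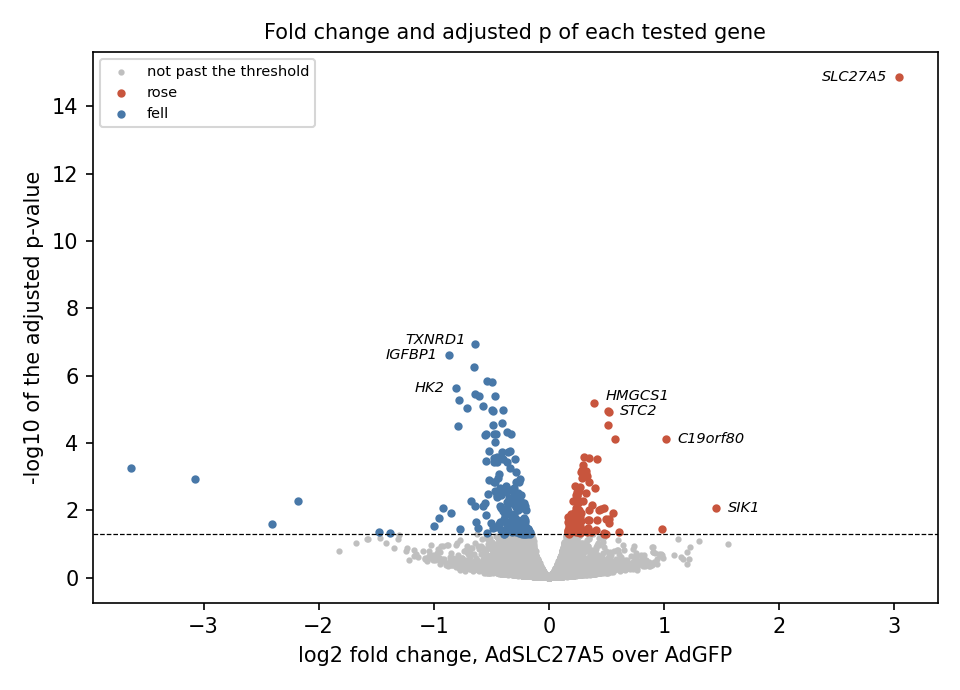
Each point is 1 of 15013 tested genes, with the log2 fold change of AdSLC27A5 over AdGFP on the x axis and -log10 of the edgeR adjusted p on the y axis; the dashed line marks an adjusted p of 0.05. SLC27A5 stands apart at 3.04, 111 genes are coloured as rose and 186 as fell, and most coloured points lie within 1 log2 unit of 0.

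The genes that rose most after SLC27A5 by the fixed rule included C19orf80, now named ANGPTL8, a secreted regulator of lipoprotein lipase, at 7.34 ± 0.761 CPM against 3.63 ± 0.220 CPM. Its log2 fold change was 1.02 (SE 0.13; edgeR adjusted p = 7.7e-05). INHBE, which encodes a hormone subunit made in liver, rose by 0.57 (SE 0.072; adjusted p = 7.7e-05), and SESN2, a stress-induced sestrin, by 0.53 (SE 0.057; adjusted p = 1.2e-05). PMAIP1, the pro-apoptotic protein NOXA, rose by 0.56 (SE 0.12; adjusted p = 0.012). DHRSX, FER1L6 and CCDC159 rose by 0.98 (SE 0.24), 0.61 (SE 0.15) and 0.52 (SE 0.11), with adjusted p-values of 0.036, 0.045 and 0.019. C19orf80 lies inside DOCK6, CCDC159 overlaps RAB3D and TMEM205, and FER1L6 overlaps antisense genes, all on the other strand, so without stated strand handling their counts can hold reads of those genes. DHRSX lies in the pseudoautosomal region, where X and Y hold copies of the sequence, and its counts of 538, 281 and 219 with AdSLC27A5 were uneven. DHRSX also holds the 3' UTR word GTTGTCA, which was found in 62 of 175 searched genes that fell. Its call ended with DESeq2 (adjusted p = 0.30), limma-voom and thinning, and without AdGFP replicate 2 or 3 or AdSLC27A5 replicate 1, where its log2 fold change was 0.44. Calls also ended for PMAIP1 without AdSLC27A5 replicate 2 or 3 (adjusted p up to 0.075), for FER1L6 without AdGFP replicate 2 or 3 or AdSLC27A5 replicate 1 or 3 (up to 0.24), with limma-voom and with total counts only, and for CCDC159 without AdGFP replicate 1 or 3 or AdSLC27A5 replicate 2 or 3 (up to 0.11).

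Among the genes that fell most, IGFBP1 went from 66.9 ± 3.43 CPM to 36.5 ± 4.05 CPM, a log2 fold change of -0.87 (SE 0.067; edgeR adjusted p = 2.4e-07). HK2, the hexokinase that opens glycolysis in many tumours, went from 28.7 ± 1.85 CPM to 16.4 ± 1.30 CPM (-0.81, SE 0.075; adjusted p = 2.4e-06). HIST1H2BK, a histone H2B gene, IAH1, an esterase homologue, and TMEM222, a transmembrane protein, had log2 fold changes of -0.79 (SE 0.092), -0.78 (SE 0.078) and -0.71 (SE 0.075), with adjusted p-values of 3.1e-05, 5.4e-06 and 9.1e-06. NATD1, the pseudogene DUXAP10 and FAM105A, now OTULINL, had log2 fold changes of -0.92 (SE 0.18), -0.85 (SE 0.18) and -0.77 (SE 0.19), with adjusted p-values of 0.0083, 0.012 and 0.035. IGFBP1 is on chromosome 7 from 45888357 to 45893668 and overlaps no annotated gene, HK2 is on chromosome 2 from 74833981 to 74893359 with a noncoding gene on the other strand, and IAH1 overlaps ADAM17 on the other strand. Of these genes HK2, IAH1 and TMEM222 hold the 7 bases GTTGTCA in the 3' UTR, and NATD1 the related word CCCGTTG. Calls ended for NATD1 without AdGFP replicate 3 or AdSLC27A5 replicate 3 (adjusted p up to 0.061), for FAM105A with limma-voom and without any 1 library but AdGFP replicate 2 (up to 0.12), and for DUXAP10 with DESeq2 (0.14), without AdSLC27A5 replicate 2 or 3 (up to 0.077) and without AdGFP replicate 2, where its log2 fold change was -0.50. Histone and pseudogene families share sequence, so the counts of HIST1H2BK and DUXAP10 are uncertain.

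Of the 297 genes, 9 changed at least 2-fold, 3 upward and 6 downward, and they are named here after their values were seen. Besides SLC27A5 and C19orf80, SIK1, a salt-inducible kinase, rose by 1.46 (SE 0.29; edgeR adjusted p = 0.0085), yet its counts with AdSLC27A5 were 912, 935 and 253 against 218, 250 and 255 with AdGFP. SIK1 has a near-identical copy, LOC102724428, with a log2 fold change of 0.27 (adjusted p = 0.012), and the counts of both summed rose by 0.48 (SE 0.076; adjusted p = 0.0010). Those that fell were LOC100132057, ASMTL, HS6ST1P1, SLX1B, LOC105374985 and HIST1H3D, a histone H3 gene with counts of 13, 23 and 15 against 1, 2 and 1. ASMTL had uneven counts of 161, 40 and 85 with AdGFP against 40, 33 and 38 with AdSLC27A5, and SLX1B of 36, 13 and 70 against 13, 3 and 8. SLX1B has a paralog, SLX1A, and the summed counts of both did not pass (adjusted p = 0.086). ASMTL is pseudoautosomal like DHRSX, and 2 of the 11 tested genes of that region passed. Calls ended for ASMTL without any 1 library but AdGFP replicate 2 (adjusted p up to 0.19), with a log2 fold change of -0.81 without AdGFP replicate 1, for LOC100132057 without any but AdGFP replicate 1 (up to 0.21), for SLX1B without AdGFP replicate 3 or AdSLC27A5 replicate 2 or 3 (up to 0.18) and for SIK1 without AdSLC27A5 replicate 2 (0.070). With limma-voom these 4 genes were not called, nor was SIK1 with DESeq2 (0.19), ASMTL and LOC100132057 with thinning, or ASMTL with a filter of at least 1 CPM in 3 libraries (0.053). The number of genes changed at least 2-fold was 2 with DESeq2, 5 with limma-voom, 3 with a filter of at least 1 CPM in 3 libraries, 2 in a test against a fold of 1.5 and 26 without a filter. DESeq2 gave no adjusted p for the 6 that fell, so it did not judge them, and its log2 fold change for HIST1H3D was -3.74.

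Of 21 tested genes of the ATF4 integrated stress response, which raises amino acid supply and stress proteins, 9 rose, 0 fell and 12 did not pass, while 15 rose adjusted over the list alone, and 2 lay below 0. The median log2 fold change was 0.20, and camera called the list upward (adjusted p = 5.9e-23; adjusted p = 0.022 with an estimated correlation). STC2, a secreted glycoprotein, went from a mean of 118 CPM to 169 CPM (0.51, SE 0.055; edgeR adjusted p = 1.1e-05). SESN2 went from 34.8 ± 1.05 CPM to 50.2 ± 2.44 CPM. CHAC1, which degrades glutathione, rose by 0.52 (SE 0.060; adjusted p = 2.9e-05), and TRIB3, a pseudokinase, by 0.42 (SE 0.059; adjusted p = 2.9e-04). In contrast, 0 of 21 members of the ER unfolded protein response passed over all genes or adjusted over the list alone, and 17 lay above 0. Among them HSPA5, CANX, MANF and SEL1L had log2 fold changes of 0.12, 0.094, 0.12 and -0.10, with adjusted p from 0.16 to 0.35. camera called this list upward (adjusted p = 0.021), but not with an estimated correlation (adjusted p = 0.45), with total counts only (adjusted p = 0.070) or without AdGFP replicate 3 or AdSLC27A5 replicate 2 or 3 (adjusted p up to 0.11).

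**Figure D3:**
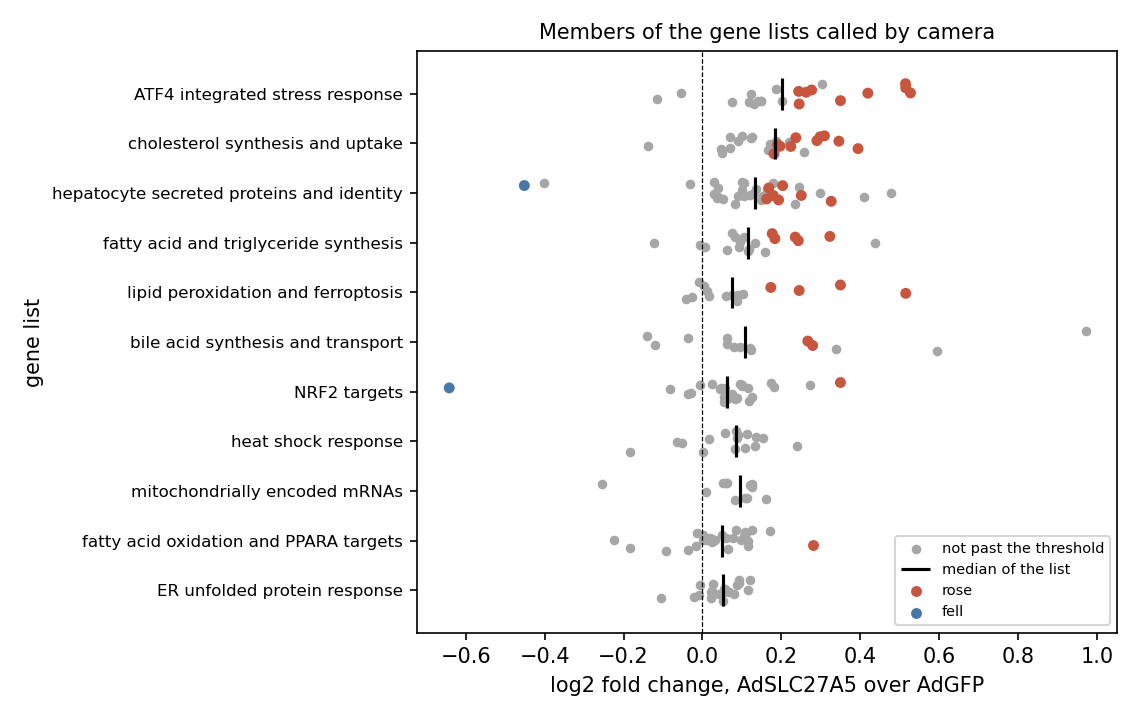
Log2 fold change of each tested member of the 11 gene lists that camera called with the preset correlation, 1 point per gene, coloured where the gene passed the edgeR test, with a black bar at the median of the list. The medians lie above 0 in all 11 lists, highest at 0.20 for the ATF4 integrated stress response and 0.18 for cholesterol synthesis, while TXNRD1 at -0.64 and G6PC at -0.45 are the points that fell.

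Of 24 tested genes of cholesterol synthesis and uptake 10 rose, 0 fell and 14 did not pass, with 17 that rose and 1 that fell adjusted over the list alone. The median was 0.18, and camera called the list upward (adjusted p = 5.9e-23; adjusted p = 0.028 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, went from 273 ± 4.95 CPM to 359 ± 10.2 CPM (0.39, SE 0.040; edgeR adjusted p = 6.3e-06). INSIG1, which retains sterol sensors in the ER, rose by 0.35 (SE 0.049; adjusted p = 2.9e-04). The sterol enzymes MSMO1 and SQLE rose by 0.31 (SE 0.043; adjusted p = 2.6e-04) and 0.30 (SE 0.044; adjusted p = 4.6e-04).

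Of the 19 tested genes of fatty acid and triglyceride synthesis, 5 rose and 0 fell, and 9 rose adjusted over the list alone. camera called the list upward at a median of 0.12 (adjusted p = 7.1e-09), but not with an estimated correlation (adjusted p = 0.16). MLXIPL, the glucose-responsive transcription factor ChREBP, rose by 0.32 (SE 0.057; edgeR adjusted p = 0.0031). The stearoyl-CoA desaturase SCD rose by 0.24 (SE 0.042; adjusted p = 0.0035), the fatty acid synthase FASN by 0.24 (SE 0.044; adjusted p = 0.0038), and ACLY, which supplies acetyl-CoA, by 0.18 (SE 0.041; adjusted p = 0.024). The call of ACLY ended without any 1 of AdGFP replicates 2 and 3 and AdSLC27A5 replicates 1, 2 and 3, with adjusted p up to 0.11, and with total counts only. Of 27 genes of fatty acid oxidation and PPARA targets 1 rose, also adjusted over the list alone: PLIN2, which coats lipid droplets, at a mean of 135 CPM against 111 CPM (0.28, SE 0.043; adjusted p = 7.4e-04). ACADVL and DECR1 of that list had log2 fold changes of 0.12 and 0.13 and did not pass. camera called the list (adjusted p = 0.012) but not with an estimated correlation (adjusted p = 0.33) or without AdSLC27A5 replicate 2 (adjusted p = 0.095). Fatty acid uptake and activation, a list that holds other SLC27 genes together with genes of other families, was not called (camera adjusted p = 0.25). Its mean of -0.0092 was below 0 while its median of 0.027 and its test lay above. In it 1 of 16 genes rose, ACSL5 at 0.33 (adjusted p = 0.044), also adjusted over the list alone, whereas ACSL4 and DBI had values of 0.018 (SE 0.054) and 0.077 (SE 0.048).

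Of 14 tested genes of bile acid synthesis and transport 2 rose and 0 fell, and 4 rose adjusted over the list alone. The 2 genes were KLB, the co-receptor of the gut hormone FGF19, at 0.28 (SE 0.058; edgeR adjusted p = 0.012), and SLC51B, a subunit of the bile acid exporter, at 0.27 (SE 0.058; adjusted p = 0.016). NR1H4, the bile acid receptor FXR, and AKR1D1, a bile acid reductase, had log2 fold changes of 0.34 (SE 0.12) and 0.97 (SE 0.36) that did not pass. The counts of AKR1D1 were low, at 12, 15 and 8 with AdGFP and 15, 22 and 36 with AdSLC27A5. Its log2 fold change ran from 0.58 to 1.18 over the leave-outs. camera called the list upward (adjusted p = 4.1e-04), but not with an estimated correlation (adjusted p = 0.085). The call of KLB ended without AdGFP replicate 2 or AdSLC27A5 replicate 3 (adjusted p up to 0.073) and that of SLC51B without AdSLC27A5 replicate 2 or 3 (adjusted p up to 0.096).

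Among hepatocyte secreted proteins and identity genes, 7 of 34 rose, 1 fell and 26 did not pass, with 19 that rose and 1 that fell adjusted over the list alone. camera called the list upward at a median of 0.13 (adjusted p = 4.4e-11; adjusted p = 0.022 with an estimated correlation). APOA1, the main protein of high-density lipoprotein, rose by 0.33 (SE 0.050; edgeR adjusted p = 6.8e-04). HNF4A, a transcription factor of hepatocyte identity, rose by 0.19 (SE 0.042; adjusted p = 0.019), and TF, which encodes transferrin, by 0.17 (SE 0.036; adjusted p = 0.016). G6PC, the glucose-6-phosphatase that releases glucose from liver, went the other way at -0.45 (SE 0.065; adjusted p = 3.7e-04). The calls of TF and HNF4A ended without AdGFP replicate 2 or 3 or AdSLC27A5 replicate 2 or 3, and that of TF also without AdSLC27A5 replicate 1, with adjusted p up to 0.10 and 0.13. APOA1 and HNF4A overlap antisense genes, and the 3' UTR of HNF4A holds the words CCGTTGT and CCCGTTG.

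The genes of NRF2, the transcription factor of the antioxidant response, did not follow TXNRD1. TXNRD1 went from 330 ± 19.3 CPM to 211 ± 7.48 CPM, a log2 fold change of -0.64 (SE 0.047; edgeR adjusted p = 1.1e-07). It lies on chromosome 12 from 104215779 to 104350305, overlaps EID3 on the same strand and an antisense gene, and holds GTTGTCA at base 342 of its longest annotated 3' UTR. Of 29 tested NRF2 targets 1 rose, 1 fell and 27 did not pass, and 24 lay above 0. Adjusted over the list alone, 5 rose and 1 fell. NQO1, GCLM and HMOX1 had log2 fold changes of 0.063 (SE 0.044), 0.047 (SE 0.070) and 0.12 (SE 0.053), and those of OSGIN1 and EPHX1 were 0.27 (SE 0.071) and 0.17 (SE 0.054), none past the threshold. OSGIN1 passed without AdGFP replicate 1 (adjusted p = 0.015) and without a filter on low counts. The sign of GCLM turned without AdGFP replicate 1 or AdSLC27A5 replicate 2, to -0.028 at the lowest. NFE2L2, which encodes NRF2, and KEAP1, its inhibitor, had values of -0.065 (SE 0.045) and 0.025 (SE 0.048), and KEAP1 was at -0.0054 without AdSLC27A5 replicate 1. camera called the list upward at a median of 0.063 (adjusted p = 0.0031), but not with an estimated correlation (adjusted p = 0.47) or without AdSLC27A5 replicate 2 (adjusted p = 0.058).

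The member of that list that rose was SLC7A11, the cystine transporter, at 0.35 (SE 0.077; edgeR adjusted p = 0.019), a call that ended without AdGFP replicate 3 or AdSLC27A5 replicate 2 or 3 (adjusted p up to 0.14). It is also an ATF4 target and a member of the list of lipid peroxidation and ferroptosis, in which 4 of 15 genes rose and 0 fell, with the same numbers adjusted over the list alone. The others were CHAC1, SLC3A2, the partner chain of SLC7A11, at 0.25 (SE 0.046; adjusted p = 0.0049), and POR, a cytochrome P450 reductase, at 0.17 (SE 0.045; adjusted p = 0.0498). The call of POR ended under upper-quartile scaling, total counts only, scaling without SLC27A5 and thinning, and without any 1 library but AdGFP replicate 1 (adjusted p up to 0.17). CHAC1, SLC3A2 and SLC7A11 belong to the ATF4 list as well, so these lists are not separate evidence. camera called the ferroptosis list upward (adjusted p = 1.9e-05), but not with an estimated correlation (adjusted p = 0.059).

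The mitochondrially encoded mRNAs and the heat shock response were called upward by camera with 0 members past the edgeR threshold, and neither was called with an estimated correlation (adjusted p = 0.48 and 0.45). Adjusted over the list alone, 5 members rose and 1 fell in each. Of the 12 mitochondrial mRNAs 11 lay above 0, with a median of 0.095 (camera adjusted p = 0.0031). ND2, ND4 and ND3 had log2 fold changes of 0.16 (SE 0.046), 0.13 (SE 0.043) and 0.12 (SE 0.044), and ND6, the gene on the other strand of the mitochondrial genome, of -0.26 (SE 0.083). ND2 passed without AdGFP replicate 1 or AdSLC27A5 replicate 2, ND4 without AdSLC27A5 replicate 2 and ND6 without AdGFP replicate 3, with adjusted p down to 0.0062, 0.019 and 9.9e-04, and all 3 passed without a filter on low counts. The list was not called without AdGFP replicate 3 or AdSLC27A5 replicate 1 or 3 (adjusted p up to 0.093). Of 16 heat shock genes 13 lay above 0, at a median of 0.086 (camera adjusted p = 0.0031, but 0.058 without AdSLC27A5 replicate 2). The chaperones HSP90AA1, HSPB1 and HSPE1 had values of 0.13 (SE 0.042), 0.15 (SE 0.050) and 0.14 (SE 0.045), against -0.18 (SE 0.058) for HSPA1B. HSPB1 passed without AdGFP replicate 3 (adjusted p = 0.046) and HSP90AA1 without a filter (adjusted p = 0.018). HSPA1B has a near-identical copy, HSPA1A, so its counts are uncertain.

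Cell cycle genes were not called as groups. Of 30 genes of G1/S and DNA replication 1 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.34). UNG, which removes uracil from DNA, and CCNE1, which encodes cyclin E1, had log2 fold changes of -0.22 (SE 0.052; edgeR adjusted p = 0.036) and -0.25 (SE 0.064; adjusted p = 0.045). RRM2, a subunit of ribonucleotide reductase, rose by 0.16 (SE 0.040; adjusted p = 0.038), and GINS2 had a value of -0.14 (SE 0.056). The call of RRM2 ended without any 1 library, that of UNG without any but AdSLC27A5 replicate 1, and that of CCNE1 without AdGFP replicate 2 or 3 or AdSLC27A5 replicate 2 or 3, with adjusted p up to 0.15, 0.20 and 0.21. RRM2 also lost its call with total counts only, and CCNE1, which holds the words CCGTTGT and CGTTGTA in its 3' UTR, with DESeq2 and with thinning. Of 30 genes of G2/M and mitosis only AURKA, the Aurora A kinase, passed, at 0.18 (adjusted p = 0.019), also adjusted over the list alone (camera adjusted p = 0.42). MKI67 and TOP2A had values of -0.023 (SE 0.063) and 0.084 (SE 0.038), and MKI67 turned to 0.088 without AdGFP replicate 1. Of 19 p53 targets 0 passed, and 1 fell adjusted over the list alone. The list's median of 0.012 lay above 0, and its mean of -0.015 and its test below (camera adjusted p = 0.58). Among them CCNG1 and TNFRSF10B had values of 0.071 (SE 0.060) and -0.12 (SE 0.048). Of 19 immediate early genes only DUSP1, a phosphatase of MAP kinases, fell, at -0.32 (adjusted p = 0.0053), also adjusted over the list alone (camera adjusted p = 0.24, but 0.0017 without AdGFP replicate 1 and 0.0046 without AdSLC27A5 replicate 1), while MYC and KLF6 had values of 0.055 (SE 0.048) and 0.10 (SE 0.087).

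HK2 was the 1 of 20 glycolysis genes that passed, and 2 fell adjusted over the list alone (camera adjusted p = 0.34). The list's mean of -0.045 and its test lay below 0 and its median of 0.011 above, with GAPDH at 0.047 (SE 0.036) and PKM at 0.010 (SE 0.036). PKM turned to -0.012 with total counts only. Of 19 hypoxia genes HK2 and MXI1, a repressor of MYC targets, fell, the latter at -0.28 (edgeR adjusted p = 0.038), with 2 that rose and 4 that fell adjusted over the list alone (camera adjusted p = 0.084). By fry, which does not compare a list with other genes, the hypoxia list moved downward on balance (adjusted p = 0.019) and changed in either direction (adjusted p = 9.9e-05). ERO1L and VEGFA had values of 0.078 (SE 0.044) and 0.13 (SE 0.047). Of 31 nuclear genes of oxidative phosphorylation 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.53), with ATP5B at 0.0032 (SE 0.040) and ATP5A1 at 0.046 (SE 0.039). ATP5B turned to -0.019 with total counts only. Of 41 ribosomal protein genes 0 passed either way (camera adjusted p = 0.076). That list was called upward without a filter (0.019), with limma-voom (0.038), and without AdGFP replicate 2 (0.0061) or 3 (0.0041) or AdSLC27A5 replicate 3 (4.3e-04), and turned downward, not called, without AdGFP replicate 1 (0.85). RPL4 was at -0.017 (SE 0.038) and RPS2 at -0.0086 (SE 0.041).

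Interferon and inflammatory genes, which respond to viral infection, did not pass the edgeR test. Both groups were infected and there was no uninfected group, so a response to infection itself could not be seen. Of 24 interferon genes 0 passed over all genes or adjusted over the list alone, and 19 lay below 0 at a median of -0.074 (camera adjusted p = 0.12, and 0.040 without AdGFP replicate 1). IFITM3 had a log2 fold change of -0.060 (SE 0.049). Of 16 NF-kB and cytokine genes 0 passed either way (camera adjusted p = 0.33, and 0.0040 without AdGFP replicate 1), with NFKB2 at 0.070 (SE 0.045) and CXCL8 at -0.091 (SE 0.090). The 3 tested histones of the replication-dependent list had a median of -0.42 and 0 passed, with 1 that fell adjusted over the list alone (camera adjusted p = 0.084, and 0.039 without AdSLC27A5 replicate 1). Of these HIST1H1C was at -0.42 (SE 0.12) and HIST1H2AM at -0.11 (SE 0.32). HIST1H1C passed without AdGFP replicate 1 (adjusted p = 0.0079) and without a filter. None of the 3 tested genes of the metallothionein list passed (camera adjusted p = 0.64), with SLC30A1 at 0.13 (SE 0.082) and MT2A at -0.17 (SE 0.13).

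Epithelial and mesenchymal genes each had 1 member past the threshold. TJP1, which encodes the tight junction protein ZO-1, fell, at -0.29 (edgeR adjusted p = 0.0070), among 12 epithelial genes, of which 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.070, but 0.038 with total counts only and 0.025 without AdGFP replicate 2). KRT8 and CLDN1 had values of -0.020 (SE 0.040) and -0.13 (SE 0.037), and CLDN1 passed with DESeq2 and with total counts only. ITGA5, the fibronectin receptor subunit, rose by 0.20 (adjusted p = 0.013) among 15 mesenchymal genes, of which 1 rose and 1 fell adjusted over the list alone. That list's median of -0.041 was below 0 and its mean of 0.0079 and its test above (camera adjusted p = 0.76), with FN1 at 0.052 (SE 0.056) and TGFBI at -0.065 (SE 0.039). Of 13 oncofetal genes LIN28B, a regulator of let-7 microRNAs, rose by 0.17 (adjusted p = 0.043), also adjusted over the list alone (camera adjusted p = 0.16), with PEG10, whose 3' UTR holds 2 copies of GTTGTCA and the words CCGTTGT and CGTTGTC, at 0.068 (SE 0.042) and CD24 at 0.077 (SE 0.046). Few markers of other cell types were tested and 0 passed over all genes. These were 3 immune markers, of which 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.62), 4 of fibroblasts or stellate cells (camera adjusted p = 0.53) and 4 of cholangiocytes (camera adjusted p = 0.58). The 2 endothelial markers tested, with a median of -0.064, were too few for camera. LYZ and CD68 were at -0.14 (SE 0.044) and 0.13 (SE 0.050), COL3A1 and PDGFRB at -0.045 (SE 0.17) and -0.18 (SE 0.27), and ANXA4 and SOX9 at 0.082 (SE 0.042) and -0.017 (SE 0.095). LYZ passed without AdGFP replicate 1 (adjusted p = 0.014).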

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

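Counting genes without the related 3' UTR words and summing near-identical copies were chosen after seeing the data. Among the 101 named genes reported, 41 were called, and 24 of these kept direction and call in every alternative fixed beforehand, SLC27A5, TXNRD1, IGFBP1, HK2, HMGCS1, SESN2, STC2 and APOA1 among them. None of the 41 reversed. Of the 60 not called, 9 passed in at least 1 alternative and 18 changed sign. SLC27A5 lay between 2.95 and 3.11 over the leave-outs.

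The cause of the differences was not tested unless the construction shows it. The count of 297 changed genes ran from 134 to 337 over the leave-outs (41 to 139 rose, 93 to 198 fell), each of which has fewer samples. Without a filter 504 genes changed, 223 up and 281 down, with 26 at least 2-fold. With total counts only 68 rose. The number changed at least 2-fold was 3 with at least 1 CPM in 3 libraries, which drops low genes, 2 with DESeq2, which gave no adjusted p for the 6 that fell, 5 with limma-voom and 2 against a fold of 1.5, a stricter test. Among searched genes, 84 that fell held none of GTTGTCA, CCGTTGT, CGTTGTA and CGTTGTC, and 80 held none of these or CCCGTTG, the other word that passed. The 11 lists called became 7 with fry directional and 19 with fry mixed, which ask another question, 3 with an estimated correlation and 7 to 14 over the leave-outs.

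The labels give both groups replicates 1 to 3. The correlations of deviations of same-numbered libraries were 0.020, 0.064 and -0.058, and of the 6 libraries only those numbered 2 correlated best with their own number. No clear pairing by number was thus seen, but so few libraries cannot exclude one. With a replicate block 409 genes changed, 173 up and 236 down, and the same 11 lists were called, while OSGIN1, ND2 and HIST1H1C were called as well (adjusted p = 0.036 each).

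By list, the camera adjusted p with an estimated correlation and then that of fry were 0.47 and 0.17 for NRF2 targets, 0.33 and 0.11 for fatty acid oxidation, 0.45 and 0.12 for the ER response, 0.48 and 0.39 for mitochondrial mRNAs, and 0.45 and 0.18 for heat shock. With an estimated correlation it was 0.085 for bile acids, 0.16 for fatty acid synthesis and 0.059 for ferroptosis. fry called hypoxia (0.019). Total counts only gave 0.070 for the ER response and 0.038 for epithelial genes, and ribosomal proteins were called without a filter (0.019) and with limma-voom (0.038). The mesenchymal list turned downward at 0.88 with at least 1 CPM in 3 libraries.

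Leave-out ranges of the adjusted p were 8.5e-05 to 0.058 for NRF2 targets, 0.0054 to 0.095 for fatty acid oxidation, 0.0061 to 0.11 for the ER response, 0.040 to 0.42 for interferon, 0.0040 to 0.91 for NF-kB, 0.025 to 0.14 for epithelial genes, 0.073 to 0.98 for oxidative phosphorylation, 2.1e-08 to 0.093 for mitochondrial mRNAs, 4.3e-04 to 0.85 for ribosomal proteins, 0.039 to 0.19 for histones, 0.0017 to 0.92 for immediate early genes, 1.2e-04 to 0.058 for heat shock and 0.37 to 0.98 for immune markers.

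Sign changes in genes not called, as leave-out ranges of log2 fold change, were GCLM -0.028 to 0.12, KEAP1 -0.0054 to 0.057, ACSL4 -0.028 to 0.094, CCNG1 -0.013 to 0.13, MKI67 -0.10 to 0.088, CXCL8 -0.22 to 0.0065, KRT8 -0.045 to 0.0072, FN1 -0.0022 to 0.14, PKM -0.00069 to 0.021, ATP5B -0.015 to 0.032, RPL4 -0.040 to 0.0051, RPS2 -0.039 to 0.023, HIST1H2AM -0.30 to 0.10, KLF6 -0.012 to 0.23, COL3A1 -0.15 to 0.039, PDGFRB -0.37 to 0.11, SOX9 -0.086 to 0.065 and TRIM28 -0.0062 to 0.061. With total counts only ACSL4 was -0.0044, PKM -0.012, ATP5B -0.019 and TRIM28 -0.0019, and with thinning COL3A1 was 0.022. What depth limits was seen only in thinning to the smallest library, which left 272 genes changed.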

Other observations

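The tests of other splits, of the NRF2 targets other than TXNRD1 and of the base before the word were chosen after the result was seen, the last because related words had been seen, and the genes of the next paragraph were chosen after their values were seen.

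Genes outside the fixed lists also fell. SLC39A6, a zinc transporter, went from 78.0 ± 3.13 CPM to 49.7 ± 2.49 CPM (SD over 3 libraries), a log2 fold change of -0.65 (SE 0.054; edgeR adjusted p = 5.4e-07). TAF15, an RNA-binding protein of the FET family, was at -0.53 (SE 0.047; adjusted p = 1.5e-06), FTSJ3, an RNA methyltransferase of ribosome assembly, at -0.49 (SE 0.044; adjusted p = 1.6e-06) and NUP50, a nuclear pore protein, at -0.46 (SE 0.045; adjusted p = 3.9e-06). CNOT7, a deadenylase of the CCR4-NOT complex, was at -0.47 (SE 0.060), APAF1, which activates caspase-9, at -0.55 (SE 0.068) and UBE2D3, a ubiquitin-conjugating enzyme, at -0.33 (SE 0.041), all past the threshold.

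More genes fell than rose, and those that fell shared short 3' UTR words: GTTGTCA occurred in 62 of 175 searched genes that fell (35.4%, 95% Wilson interval 28.7% to 42.8%), in 2 of 100 that rose and in 10.7% of 12026 not called, but median UTR lengths were 2165 bases for genes that fell and 841 for genes that rose, which accounts for part of the contrast. With UTR length, GC content and expression in the model, 5 words passed among genes that fell and 0 among genes that rose (smallest Bonferroni p = 1.0e-06, n = 175 genes, for CCGTTGT, in 26 genes against 5.17 expected, and 62 against 26.0 for GTTGTCA), consistent with repression through a short match, as a small RNA would give, although genes with 2 or more copies of GTTGTCA differed from genes with 1 by -0.010 (SE 0.0099), no effect of copy number beyond its spread. The z of GTTGTCA over 9536 genes differed by -3.16 from the lowest of 419 words of the same letters. The word was picked on these same genes, so this gap alone does not decide on UTR length or composition. GTTGTCA had the lowest z of all words in each of 2 random parts of the genes, with shifts of -0.026 (SE 0.0053) and -0.047 (SE 0.0051). The lead found in 1 part thus held in the other, so picking the word on the same genes does not account for it. This check was not among those fixed beforehand. Both parts come from the same 6 libraries, so an effect of UTR composition beyond the model's terms would recur in both and stays open. Genes with the word in the 3' UTR differed by -0.015 (SE 0.0057) from genes with it in the coding sequence only. The latter were also shifted, by -0.022 (SE 0.0047), and the word was picked for its 3' UTR excess. A mark anywhere in the transcript therefore stays open. Only 10 splits of the 6 libraries exist, too few for a share under 0.05; the real one gave 297 genes and the highest other 0, while 80 of the searched genes that fell hold none of the 5 words.

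A hypothesis for the word is the adenovirus vector itself, whose VA RNA I is cut into small RNAs in infected cells and is kept in vectors of the AdEasy kind, so that unequal virus dose may act on host mRNAs. The known start of such an RNA pairs with C before the word, and genes with C there differed by -0.057 (SE 0.013) from the others, but the related word CGTTGTC had already been seen, so this difference restates it and lends the hypothesis no support. The shift was -0.089 (SE 0.013, 70 genes) with C, -0.042 (SE 0.0053) with T, -0.034 (SE 0.0057) with A and -0.012 (SE 0.0072) with G before the word, so it was uneven among the other bases too. TIA1, a reported target of these RNAs, did not fall, at 0.086 (SE 0.069, 95% interval -0.058 to 0.23), which decided nothing at this spread. Of human microRNA hairpins 1 of 1879, and of SLC27A5 transcripts 0 of 8, hold the 7 bases that pair with CGTTGTC. The bases that pair with GTTGTCA itself were not searched for in either. The hypothesis stays open, as viral RNA was not analysed here, the virus carrying SLC27A5 is confounded with SLC27A5 itself, and an effect of SLC27A5 on another small RNA stays open.

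TXNRD1 fell by 0.64 on the log2 scale, with no overlap between the libraries of the groups. Its longest annotated 3' UTR holds 1 copy of GTTGTCA, so repression through the word may cover it. The transcripts of the 28 other NRF2 targets did not fall as a set. Their median was 0.068, far above -0.32, the value midway between 0 and TXNRD1. The bootstrap SE of this median, 0.012, is over genes and not over libraries. The comparison with -0.32 was set after the result was seen, so its outcome was already known and it decides nothing on NRF2 activity, which was not measured. An effect of SLC27A5 on TXNRD1 alone was not tested, and the word may be there by chance, as 10.7% of genes not called hold it. The copy in TXNRD1 has C before it, and CGTTGTC occurs in 2.06% of searched genes. The base C was singled out only after related words had been seen. HK2, IAH1 and TMEM222 hold the word too, and so do DHRSX, which rose, and PEG10, with 2 copies and a value of 0.068. It also occurs in CANX, at 0.094, and CXCL8, at -0.091, neither of them called. Of these genes only TMEM222 has C before its copy, as TXNRD1 does. IGFBP1, which fell more than TXNRD1, holds 0 copies in a 3' UTR of 577 bases.

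In the other 9 splits of the libraries, each of which keeps part of the difference between the groups, |z| of GTTGTCA lay between 4.01 and 6.06, against 9.42 in the real one. The largest |z| of any word in those splits was 8.71, for GGGATTA, and between 2 and 420 words passed in the shift model, against 10 in the real one. These counts point to a structure of the libraries in other words, and the z-values, taken over genes, do not measure the spread between libraries. By library, the shift of genes with GTTGTCA from each gene's mean was 0.019, 0.017 and 0.017 with AdGFP. With AdSLC27A5 it was -0.016, -0.018 and -0.019. The word was picked on this same contrast, so a separation of the groups was partly built in. Among the 9279 genes of the shift model not called, GTTGTCA still had the lowest z, at a shift of -0.021 (SE 0.0030).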
